A study of Mus musculus with 8 samples.

How the data were processed

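RNA from mouse proximal colon epithelium was measured in 8 libraries: per the labels, 3 with EED knocked out, 3 with EED and SATB2 and 2 with SATB2. Per the labels' protocols, RNA was extracted with TRIZOL and made into non-directional mRNA libraries. The deposited raw table holds counts per gene symbol, which the authors made with featureCounts in its default unstranded mode. Per the submitters' processing notes, Trim Galore, STAR, featureCounts and DESeq2 were used with genome build GRCm38, without stated versions or annotation release. The deposited normalized table holds a signal that the authors made by dividing each raw count by 1 size factor per library. It lists 14796 symbols, of which 99.7% of those matched were protein coding. Both tables have 17 columns, of which 9 match no sample of this series record and were not used.

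The raw table lists 54735 symbols, of which 25751 had 0 counts in all 8 libraries. Of all symbols 54000 (98.7%) matched exactly 1 gene of GENCODE mouse release M21, which gave the coordinates. The libraries held 16.2e6, 16.8e6 and 16.9e6 counts (EED knockout), 25.4e6, 17.1e6 and 17.1e6 (double knockout) and 23.5e6 and 16.6e6 (SATB2 knockout). Pearson correlations of log2 CPM within groups were 0.968 to 0.984.

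Counts were fitted with edgeR 4.0.16 in R 4.3.3, with all 8 libraries in 1 quasi-likelihood model with robust estimation and 5 residual degrees of freedom. TMM scaling was used. After filterByExpr with its defaults (minimum count 10, minimum total 15), 15924 genes holding 99.9% of all counts were tested. The filter keeps a gene with enough counts in as many libraries as the smallest group holds, whichever these are. A gene without reads in 1 group was thus tested only because of other groups, so its direction against that group was fixed. A gene with too few reads in 1 group to pass by that group was likewise tested through others, which favoured its being lower there. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The 3 comparisons were the double knockout against each single knockout and the SATB2 against the EED knockout. They share libraries, so they are not independent, and overlaps between their calls are not given. Log2 CPM used a prior count of 2. Where a group had 0 counts, the fold is given as a lower bound from 3 counts over that group (the exact upper 95% limit for 0 counts, rounded). Where it had 1 to 3 counts, a count ratio with an exact interval is given. Both cover counting error only.

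Before the data were examined, 25 gene lists were fixed: small-intestinal enterocyte digestion and absorption, dietary lipid absorption and lipoproteins, ileal bile acid handling, Paneth cell, colonic epithelium, intestinal regional transcription factors, PRC2 subunits, HOX clusters, developmental transcription factors typical of PRC2 targets, CDK inhibitors, intestinal stem cell and WNT targets, proliferation, fetal and regenerative epithelium, goblet cell, enteroendocrine cell, tuft cell, gastric and squamous epithelium, lymphocytes, myeloid cells, mesenchyme with muscle, endothelium and glia, interferon-stimulated genes, MHC class II, immediate early and heat shock response, mitochondrially encoded transcripts and sex-linked transcripts. Each was tested with camera (limma 3.58.1) with its preset inter-gene correlation of 0.01, adjusted over the 25 lists of a comparison. Counts of list members are over those that passed the filter. These were 8 of 17 Paneth cell, 7 of 16 gastric and squamous, 30 of 39 HOX and 14 of 19 mesenchyme genes. They were 37 of 50 developmental transcription factors. The comparisons, the alternatives and the rule for named genes were fixed at the same time. By that rule the named genes are Eed and Satb2, the 8 largest rises and falls per comparison (5 and 5 for the single knockouts) and up to 4 members per list with the smallest adjusted p. The rises and falls had to be called with a log2 fold change of at least 1 and a mean of at least 5 CPM in the higher group, with every library of 1 group above every library of the other. Symbols of predicted genes were left out of them. The report names part of the list members that the rule gave. That part was chosen after their values were seen, with preference for members whose call did not depend on a single library. The 8 genes drawn were also chosen after their values were seen.

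The method was tested on simulated data with 67, 67 and 66 genes changed 1.5-fold, 2-fold and 4-fold. It recovered 14.9%, 50.7% and 78.8% of them in the double against the SATB2 knockout, with 8.20% false among its calls. For the double against the EED knockout it recovered 22.4%, 58.2% and 75.8% (5.56% false), and for the SATB2 against the EED knockout 11.9%, 40.3% and 77.3% (10.4% false). The false shares lay above the 0.05 of the threshold. Only these 200 genes and 1 shifted list were changed, whereas 3704, 3509 and 4715 genes were called in the data. The same adjusted threshold was therefore stricter in the simulation, so these shares do not describe the reported fits. A shifted list was called in each comparison, and 0 of 24 unchanged lists were, with the preset and with the estimated correlation. The simulated genes varied independently of each other, so this cannot show how camera calls lists of correlated genes. The estimated correlation of the real lists reached 0.795 (lymphocytes).

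The alternatives fixed beforehand were DESeq2 size factors or upper-quartile factors, no low-count filter or a stricter filter, DESeq2 1.42.0, limma voom, limma-trend on the authors' normalized values, fits of 2 groups only, non-robust estimation, replicate number as a block, a fold threshold with glmTreat, leaving out each library, fry, and camera with an estimated correlation. Added after seeing the data were the 6 female libraries only, sex as a covariate, and the symbols of the authors' normalized table only. Counting ignored strand, so reads in exons shared by 2 genes cannot be assigned by strand. Of 216 genes checked, 18 share at least 10% of their exonic bases with another gene, among them Apoa4 (34.9%), Stat1 (30.8%), Cdkn1c (30.7%), Fgf15 (24.9%), Hoxa7 (20.4%), Slc51a (17.7%), Sox17 (16.8%) and B4galnt2 (15.3%). Eed shares 6.82% and Satb2 9.05%. Hmga1b, Hsd3b3, Klk1b22, Defa24, Ang4, Akr1c18, Oas1f, Cfhr2 and Lyz1 have close paralogs that may share reads. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.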

Results

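The data are gene-level read counts from bulk RNA sequencing of mouse proximal colon epithelium after tamoxifen given to delete the targeted genes. Tamoxifen was given at 1 mg per 20 g body weight on 4 consecutive days, and the samples carry the time label day 7. Epithelium was released with 10 mM EDTA, so the libraries hold epithelial cells together with whatever other cells came loose with them. The EED knockout (3 libraries) targeted EED, a core subunit of PRC2, the Polycomb complex that methylates histone H3 at silenced genes. The SATB2 knockout (2 libraries) targeted SATB2, a DNA-binding chromatin factor of the colonic epithelium. The double knockout (3 libraries) targeted both. The libraries held 16.2e6 to 25.4e6 counts each. Values below are CPM (counts per 1e6 of the TMM-scaled total of tested genes). They are given as mean ± SD over 3 EED knockout, 3 double knockout or 2 SATB2 knockout libraries.

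No group without a knockout was analysed here. Each comparison therefore sets 1 knockout group against another, and neither the effect of a single knockout nor an interaction was estimated. The labels do not say whether replicate libraries came from separate mice, so p-values measure only the spread between these samples. EED knockout replicate 3 and double knockout replicate 2 had more reads of the Y-linked gene Ddx3y (808 and 769) than of Xist (61 and 1), while the other 6 libraries had 0 Ddx3y reads, so the EED and the double knockout group each hold more than 1 mouse. Mitochondrially encoded transcripts took 10.0%, 8.40% and 4.28% of counts in the EED knockout libraries, 5.07%, 6.98% and 3.47% in the double knockout and 5.08% and 3.37% in the SATB2 knockout. The first principal component of log2 CPM (43.9% of the variance) separated the SATB2 knockout from the other libraries, and the second (31.0%) separated the double knockout.

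The targeted genes were examined first. Eed (chromosome 7, 89954654 to 89980983, GRCm38) stood at 13.1 ± 1.35 CPM in the EED knockout and 12.9 ± 0.293 CPM in the double knockout, against 40.7 ± 0.367 CPM in the SATB2 knockout. It was 3.15-fold lower in the double than in the SATB2 knockout (edgeR adjusted p = 5.56e-05) and did not differ detectably between the double and the EED knockout (log2 fold change -0.02 ± 0.11 SE, edgeR adjusted p = 0.939). Satb2 (chromosome 1, 56793981 to 56978650) stood at 165 ± 15.4 CPM in the EED knockout, 120 ± 4.96 CPM in the SATB2 knockout and 53.1 ± 17.3 CPM in the double knockout. It was lower in the double knockout than in the EED knockout by 1.63 ± 0.20 on the log2 scale (log2 fold change -1.63, edgeR adjusted p = 0.000765). The difference between the SATB2 and the EED knockout was not called (log2 fold change -0.46 ± 0.22 SE, edgeR adjusted p = 0.151), whereas a fit of those 2 groups alone gave an adjusted p of 0.0225, as did leaving out double knockout replicate 1 (0.0179). Against the SATB2 knockout the double knockout was lower (log2 fold change -1.17 ± 0.22 SE, edgeR adjusted p = 0.00629, and 0.0585 without SATB2 knockout replicate 1). Which exons were deleted is not stated. Counts over a whole gene can include exons outside the deleted part, and incomplete deletion would leave reads too. Reads of Satb2 or Eed in a knockout therefore do not measure how complete the deletion was.

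**Figure D1:**
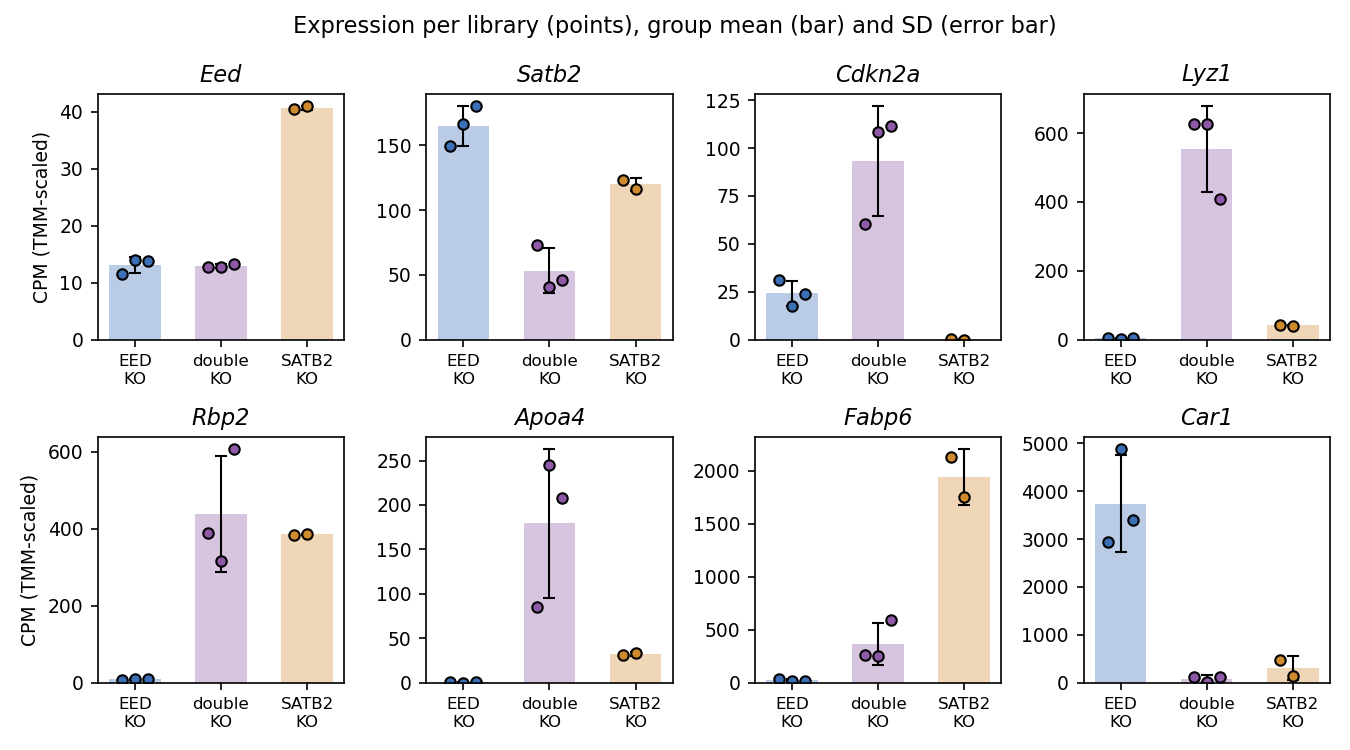
CPM (vertical axes, linear, each starting at 0) of 8 genes in the EED knockout, double knockout and SATB2 knockout. Points are libraries, bars are group means and error bars are SD. Eed is at about 13 CPM in both groups with Eed targeted against 40.7 in the SATB2 knockout. Lyz1 has its highest mean, 554 CPM, in the double knockout, and Car1 has its highest mean, 3743 CPM, in the EED knockout.

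The double knockout against the SATB2 knockout shows what differed with Eed targeting in epithelium with Satb2 targeted as well. Developmental transcription factors that had few or no reads in the SATB2 knockout were expressed in the double knockout, among them the homeobox genes En2 at 23.1 ± 7.71 CPM and Six3 at 14.0 ± 6.89 CPM, both with 0 counts in the SATB2 knockout. The cell-cycle inhibitor gene Cdkn2a (chromosome 4, 89274471 to 89294653) stood at 93.4 ± 28.8 CPM against 0.0465 ± 0.0658 CPM. Lyz1 (chromosome 10, 117287797 to 117292868), the lysozyme of Paneth cells, was 13.5-fold higher, at 554 ± 126 against 40.9 ± 2.42 CPM. Of 7 genes of ileal bile acid handling 5 were lower (list adjusted p = 0.212 with an estimated correlation), such as Slc51a, a subunit of the basolateral bile acid exporter, at 117 ± 42.0 against 503 ± 91.6 CPM. In all, 3704 of 15924 tested genes changed (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 2277 higher and 1427 lower in the double knockout. Of those that differed at least 2-fold, 1659 were higher and 175 lower.

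Of the list of developmental transcription factors typical of PRC2 targets, 35 of 37 tested members were higher and 0 lower (36 and 0 adjusted over the list alone), with a median log2 fold change of 7.77. In this list 24 members had no reads in 1 of the groups, and the median was 5.46 with those at their bound (3 counts over the group). Of the list's 50 members 37 passed the filter. Those without reads in the SATB2 knockout passed it through the other groups, so for them a rise was the only possible direction. Camera gave an adjusted p of 1.18e-22 and an adjusted p of 0.212 with an estimated correlation. Beside En2, the genes that the naming rule gave as the largest rises by fitted log2 fold change were Sox17 (at least 218-fold), Sim2 (at least 170-fold), Six3 (at least 171-fold) and Dmrt2 (at least 143-fold), all transcription factors of embryonic patterning or organ formation, and the interferon-responsive gene Ifi44l (at least 181-fold). En2 was at least 281-fold higher. Cdkn2a had a count ratio of 1674 (exact 95% interval 463 to 13830, counting error only), and its log2 fold change of 10.61 was 13.74 without SATB2 knockout replicate 1 and 9.81 without replicate 2. Gbp2b, an interferon-inducible guanylate-binding protein gene, stood at 262 ± 245 CPM against 0.0542 ± 0.0109 CPM, and its call (edgeR adjusted p = 0.0140) was lost without SATB2 knockout replicate 1 (0.125) or 2 (0.0819). Its log2 fold change of 12.10 was 11.04 without double knockout replicate 2. With limma voom the calls of Gbp2b (adjusted p = 0.323) and Sox17 (0.0693) were lost.

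The HOX clusters list had 16 of 30 members higher and 2 lower (17 and 2 adjusted over the list alone), with a median of 0.98 and a camera adjusted p of 9.05e-05 (adjusted p = 0.212 with an estimated correlation). The median was 1.71 without SATB2 knockout replicate 2, 1.49 without replicate 1 and 1.65 with no low-count filter. Hoxd13 was at least 62.1-fold and Hoxc11 at least 86.4-fold higher, while Hoxa10, already at 19.7 ± 3.72 CPM in the SATB2 knockout, was 3.25-fold higher. In the gastric and squamous epithelium list 6 of 7 tested members were higher and 0 lower (6 adjusted over the list alone; median 6.88, or 4.30 with the 4 members that had no reads in 1 group at their bound, and 3.81 with no low-count filter; camera adjusted p = 0.000101, and adjusted p = 0.212 with an estimated correlation). Its highest member was Sox2, at 9.75 ± 4.40 CPM with 0 counts in the SATB2 knockout. This list holds 16 genes, of which only 7 passed the filter. Among 20 intestinal regional transcription factors, 4 were higher and 9 lower and the list was not called (camera adjusted p = 0.167; the median of -0.23 and the mean of 0.56 differ in sign). Gata4, Pdx1 and Onecut2, factors of the proximal small intestine and foregut, were 28.9-fold, 22.0-fold and 34.7-fold higher, and the intestinal master regulator Cdx2 was 1.78-fold lower. Of 12 PRC2 subunits and partners, 2 were higher and 3 lower (camera adjusted p = 0.305). Epop was 4.58-fold higher, and Jarid2 was 1.62-fold lower beside Eed itself.

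Ileal bile acid handling had 0 of 7 members higher and 5 lower (the same counts adjusted over the list alone), with a median of -1.47 (camera adjusted p = 9.05e-05, and adjusted p = 0.212 with an estimated correlation). Slc51a fell 4.29-fold and its partner Slc51b 2.77-fold, and Nr1h4, which encodes the bile acid receptor FXR, fell 2.34-fold. The cytosolic carrier Fabp6 (5.28-fold) and the apical transporter Slc10a2 (3.46-fold) also fell, with adjusted p of 0.0639 and 0.0619 without SATB2 knockout replicate 1. Small-intestinal enterocyte genes moved both ways, 4 of 30 higher and 8 lower (5 and 10 adjusted over the list alone; median -0.14 and mean 0.04, which differ in sign, camera adjusted p = 0.109). This list was called lower without double knockout replicate 3 (median -0.22, adjusted p = 0.0267), without SATB2 knockout replicate 2 (median -0.33, 0.0446) and with no low-count filter (0.0388), and its median ranged up to 0.01 with 1 library left out. The sulfate transporter Slc13a1 was 6.75-fold and the trehalase gene Treh 5.00-fold lower. Dietary lipid absorption had 6 of 19 members higher and 0 lower (the same adjusted over the list alone; median 0.53, camera adjusted p = 0.0727), among them the lipoprotein receptor gene Scarb1, 4.07-fold higher. This list was called higher without double knockout replicate 2 (median 0.71, adjusted p = 0.00880), EED knockout replicate 2 (0.0303) or SATB2 knockout replicate 1 (0.0305), with no low-count filter (0.0376) and in the 6 female libraries only (0.00551). Its median ranged from 0.29 to 0.71 with 1 library left out. The other genes with the largest falls under the naming rule were BC049987 (139-fold, log2 fold change -7.12, or -8.12 without double knockout replicate 1), Hmga1b (38.3-fold), Slco2b1, an organic anion transporter (9.03-fold), Cfhr2 (8.75-fold), Hsd3b3 (5.92-fold) and Spink12 (5.61-fold). The calls of the last 2 were lost when single libraries were left out (adjusted p of 0.142 for Hsd3b3 without SATB2 knockout replicate 1, 0.0552 with no low-count filter and 0.0539 in the 6 female libraries only, and for Spink12 0.0737 without SATB2 knockout replicate 2 and 0.0558 without double knockout replicate 3). Their log2 fold changes moved from -2.56 to -1.92 (Hsd3b3, without SATB2 knockout replicate 1) and from -2.49 to -1.79 (Spink12, without SATB2 knockout replicate 2).

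Paneth cell genes had 6 of 8 tested members higher and 0 lower (7 adjusted over the list alone), with a median of 2.38 (camera adjusted p = 9.05e-05, and adjusted p = 0.212 with an estimated correlation), including the metalloproteinase gene Mmp7, 2.79-fold higher. The list holds 17 genes, mostly alpha-defensins, of which only 8 passed the filter. Goblet cell genes had 7 of 16 higher and 0 lower (9 and 1 adjusted over the list alone; camera adjusted p = 0.0102, and adjusted p = 0.383 with an estimated correlation), with Reg4 at 1025 ± 167 against 209 ± 11.2 CPM. Fetal and regenerative epithelium had 12 of 15 higher and 0 lower (12 adjusted over the list alone), with a median of 1.96 (camera adjusted p = 3.99e-07, and adjusted p = 0.212 with an estimated correlation). Its examples were Il1rn (4.20-fold), Anxa1 (3.76-fold) and Clu (7.64-fold). Intestinal stem cell and WNT target genes had 11 of 22 higher and 0 lower (13 adjusted over the list alone; median 0.70, camera adjusted p = 9.05e-05, and adjusted p = 0.212 with an estimated correlation), with Sox9 2.15-fold and Cd44 2.22-fold higher. With 1 SATB2 knockout library left out, the log2 fold change of Onecut2 was 4.40 (replicate 1) or 6.15 (replicate 2) against 5.12, and that of Clu 3.59 (replicate 1) against 2.93. Proliferation genes had 13 of 27 lower and 0 higher (15 adjusted over the list alone), with a small median of -0.32 (camera adjusted p = 9.05e-05, and adjusted p = 0.373 with an estimated correlation). Interferon-stimulated genes had 13 of 19 higher and 0 lower (15 adjusted over the list alone; median 1.70, camera adjusted p = 7.88e-06, and adjusted p = 0.383 with an estimated correlation). Among these Rsad2 was 9.92-fold and Isg15 4.79-fold higher.

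Markers of cells outside the epithelium were also measured. Whether such cells contributed to the changes of other lists was not tested here or in the SATB2 against the EED knockout. Mesenchyme, muscle, endothelium and glia markers had 6 of 14 higher and 0 lower (8 adjusted over the list alone; median 2.00, camera adjusted p = 0.00269, and adjusted p = 0.383 with an estimated correlation). Col3a1, a fibrillar collagen gene of fibroblasts, stood at 11.5 ± 5.07 against 1.61 ± 0.352 CPM. Myeloid markers had 5 of 14 higher and 0 lower (6 adjusted over the list alone; median 1.73, camera adjusted p = 0.0111, 0.0642 without double knockout replicate 2, 0.0708 with fry, and adjusted p = 0.597 with an estimated correlation), with Csf1r at 2.41 ± 0.699 against 0.279 ± 0.132 CPM (log2 fold change 3.04, or 3.65 without SATB2 knockout replicate 1). Of 18 lymphocyte markers 0 changed (median 1.03, camera adjusted p = 0.360). MHC class II genes had 1 of 7 lower, H2-Aa (median -0.42, camera adjusted p = 0.0425, and adjusted p = 0.597 with an estimated correlation). Leaving out EED knockout replicate 3, double knockout replicate 1 or 3, or SATB2 knockout replicate 1 ended that list's call (adjusted p of 0.0522, 0.127, 0.0873 and 0.126), as did fry (0.203). Not called were the lists of colonic epithelium (5 of 24 higher, 4 lower), CDK inhibitors (2 of 7 higher, 2 lower; the median of -0.28 and the mean of 1.39 differ in sign, and fry called the list higher, adjusted p = 0.00502), enteroendocrine cells (8 of 25 higher, 1 lower), tuft cells (2 of 12 higher), immediate early and heat shock genes (1 of 14 higher, 2 lower), mitochondrially encoded transcripts (0 of 13) and sex-linked transcripts (0 of 5), with camera adjusted p from 0.1 to 0.871. Enteroendocrine cell genes (median 0.56, range 0.12 to 0.80 with 1 library left out) were called higher without double knockout replicate 3 (0.0400) or SATB2 knockout replicate 1 (0.00578). Tuft cell genes (median 0.52, range 0.16 to 0.77) were called higher without double knockout replicate 2 (0.0103), in the 6 female libraries only (0.0116) and with sex as a covariate (0.0176).

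In this comparison the count of changed genes fell when either SATB2 knockout library was left out, more so without replicate 1. Either way 1 library remained in that group, so the drop cannot be credited to a trait of the library left out. Upper-quartile scaling in place of TMM gave 2535 higher and 865 lower (74.6% higher, against 61.5% in the reported fit), and sex as a covariate, chosen after seeing the data, 1812 and 874.

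The double knockout against the EED knockout shows what differed with Satb2 targeting in epithelium with Eed targeted as well. Of 30 genes of small-intestinal enterocytes 25 were higher in the double knockout, and of 24 genes of the colonic epithelium 18 were lower (list adjusted p = 0.308 for both with an estimated correlation). Rbp2 (chromosome 9, 98486115 to 98509781), the cellular retinol-binding protein of enterocytes, stood at 438 ± 151 against 8.66 ± 0.938 CPM, a 50.5-fold difference, and the apolipoprotein gene Apoa4 (chromosome 9, 46240696 to 46243459) at 179 ± 83.7 against 0.530 ± 0.407 CPM. Aqp4 (chromosome 18, 15389496 to 15410982), a water channel of the colonic epithelium list, stood at 74.0 ± 17.3 against 462 ± 105 CPM. Lyz1 was 168-fold higher, at 554 ± 126 against 3.28 ± 1.11 CPM. In all, 3509 of 15924 tested genes changed, 1843 higher and 1666 lower, of which 867 higher and 542 lower genes differed at least 2-fold.

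Of 30 small-intestinal enterocyte genes 25 were higher and 1 lower (27 and 1 adjusted over the list alone), with a median log2 fold change of 1.59 (camera adjusted p = 1.57e-15, and adjusted p = 0.308 with an estimated correlation). The amino acid transporter genes Slc6a19 and Slc7a9 were 22.3-fold and 4.31-fold higher, and Ace2, the carboxypeptidase that pairs with Slc6a19, was 10.4-fold higher. Dietary lipid absorption had 16 of 19 members higher and 1 lower (18 and 1 adjusted over the list alone), with a median of 2.94 (camera adjusted p = 2.33e-12, and adjusted p = 0.308 with an estimated correlation). Apob, the structural protein of chylomicrons, stood at 902 ± 271 against 94.4 ± 10.9 CPM, and Mogat2, which rebuilds triglycerides from absorbed monoglycerides, was 9.50-fold higher. The lower member was Pck1, the gluconeogenic enzyme, at 30.9 ± 5.58 against 145 ± 27.4 CPM. Ileal bile acid handling did not move one way, with 2 of 7 higher and 2 lower (3 and 3 adjusted over the list alone; camera adjusted p = 0.703). Fabp6 (15.3-fold) and the enterokine gene Fgf15 (14.6-fold) were higher, and Nr1h4 (1.67-fold) and the exporter gene Abcc3 (1.98-fold) were lower. The Abcc3 call (adjusted p = 0.0378) was lost without EED knockout replicate 2 or 3, double knockout replicate 3 or either SATB2 knockout replicate (0.0633 to 0.103), with no low-count filter (0.168) and with only the 2 groups compared (0.0587).

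Colonic epithelium genes had 0 of 24 higher and 18 lower (19 adjusted over the list alone), with a median of -2.06 (camera adjusted p = 3.31e-12, and adjusted p = 0.308 with an estimated correlation). Nxpe2 stood at 1.13 ± 0.684 against 78.3 ± 11.2 CPM, the glycosyltransferase gene B4galnt2 was 3.51-fold lower and Ggh, a folate hydrolase gene, was 3.86-fold lower. Among the largest falls under the naming rule were also Abca12, a lipid transporter (102-fold), Akr1c18, a steroid-metabolizing enzyme (56.6-fold), Grin3a, a glutamate receptor subunit (45.7-fold), and Mal, a protein of apical membrane sorting (32.8-fold). Car1, the colonic carbonic anhydrase, stood at 86.4 ± 68.0 against 3743 ± 1014 CPM and the proton pump gene Atp12a at 1.05 ± 1.44 against 31.5 ± 25.9 CPM. Their calls (edgeR adjusted p = 0.0237 and 0.0246) were lost with no low-count filter (0.0532 and 0.0569), and that of Atp12a with limma voom (0.0690) and in the 6 female libraries only (0.0990). They were also lost when single libraries were left out, for Car1 with each EED knockout library and with double knockout replicates 1 and 3 (0.053 to 0.0672), and for Atp12a with double knockout replicates 2 and 3 (0.0718 and 0.0618). The log2 fold change of Atp12a, -4.75, was -3.86 without EED knockout replicate 1 and -7.10 without double knockout replicate 1. Without double knockout replicate 3 that of Abca12 was -7.30 (against -6.67) and that of Mal -5.67 (against -5.04), and without replicate 1 that of Nxpe2 was -6.69 (against -6.03) and that of Akr1c18 -6.50 (against -5.82). St6galnac1, a sialyltransferase gene, was at 0.128 CPM in EED knockout replicate 1 and at 35.2 and 38.9 CPM in replicates 2 and 3, and its call (adjusted p = 0.0338) was lost without any 1 library except EED knockout replicate 1 (0.0653 to 0.184), with no low-count filter (0.0763), limma voom (0.510) or sex as a covariate (0.0570) and in the 6 female libraries only (0.295). Its log2 fold change of -10.09 was -10.69 without EED knockout replicate 1, -9.47 without double knockout replicate 1 and -11.86 without double knockout replicate 2.

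By fitted log2 fold change, which for a group at 0 counts lies above the bound given here, the largest rises under the naming rule were those of Anxa10, an annexin of gastric epithelium with 0 counts in the EED knockout (at least 93.7-fold), Enpp7, the intestinal alkaline sphingomyelinase (count ratio 904, exact 95% interval 250 to 7465), Ifi44l (count ratio 710, interval 127 to 28070), the sulfotransferase gene Sult6b2 (385-fold), the brush-border peptidase gene Mme (366-fold), Apoa4 (335-fold), the incretin gene Gip (210-fold) and Apoa1 (193-fold). Log2 fold changes that moved with EED knockout libraries were those of Enpp7 (9.67, and 12.53 without replicate 1), Ifi44l (9.10, and 11.13 without replicate 3), Mme (8.51, 9.25 without replicate 1 and 7.92 without replicate 3) and Gip (7.71, and 8.61 without replicate 3). Paneth cell genes had 5 of 8 tested members (of 17 on the list) higher and 1 lower. The counts were the same adjusted over the list alone, and Mmp7 was 4.18-fold higher. The list was called, with a median of 1.52 (camera adjusted p = 0.0297, and adjusted p = 0.488 with an estimated correlation). That call was lost without EED knockout replicate 1 (camera adjusted p = 0.0833), and with no low-count filter the median was 0.98. Goblet cell genes moved both ways, 4 of 16 higher and 5 lower (camera adjusted p = 0.814). Reg4 was 8.64-fold and Tff3 2.76-fold higher, and Bcas1 1.54-fold lower. Enteroendocrine genes had 12 of 25 higher and 5 lower (13 and 7 adjusted over the list alone; camera adjusted p = 0.0608). They were called higher with fry (0.0265), with no low-count filter (0.0197), without EED knockout replicate 2 (0.0440) or 3 (0.0424), in the 6 female libraries only (0.0492) and with sex as a covariate (0.0347). The hormone genes Cck and Gip were 10.1-fold and 210-fold higher and the granule protein gene Chga was 2.44-fold lower.

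Developmental transcription factors typical of PRC2 targets had 23 of 37 members higher and 0 lower (27 adjusted over the list alone), with a median of 2.30 (camera adjusted p = 6.06e-13, and adjusted p = 0.488 with an estimated correlation). Eed itself did not differ detectably between these groups. Zic2 stood at 7.45 ± 1.93 against 0.576 ± 0.282 CPM, En1 at 7.43 ± 2.16 against 0.615 ± 0.397 CPM and Tbx3 at 155 ± 24.5 against 42.8 ± 14.1 CPM. Zic2 had 14, 6 and 8 counts in the EED knockout libraries and 0 in the SATB2 knockout. Members with so few reads there, such as Zic2, Zic5 and Irx5, passed the filter only through the double knockout, which favoured a rise. The list's counts, median and camera result share this limit. Cdkn2a was 3.88-fold higher than in the EED knockout, while Cdkn1c and Cdkn1b, which encode CDK inhibitors of another family, were 2.31-fold and 1.55-fold lower (2 of 7 CDK inhibitors higher, 2 lower, camera adjusted p = 0.354, and called lower with fry, 0.00978). Gastric and squamous epithelium had 4 of 7 tested members (of 16 on the list) higher and 0 lower (4 adjusted over the list alone). Its median was 3.10 (camera adjusted p = 0.0236, and adjusted p = 0.488 with an estimated correlation). With 1 library left out the median ranged from 2.32 to 3.53. Sox2 was 11.9-fold higher. Gkn1, Krt4 and Krt6a had at most 5 counts in any EED knockout library and 0 in the SATB2 knockout. They passed the filter only through the double knockout, which favoured their rise and so the list's counts, median and call. Among intestinal regional transcription factors 7 of 20 were higher and 6 lower (camera adjusted p = 0.768). Cdx2 was 2.57-fold and Klf4 2.38-fold lower, and Gata6 was 1.86-fold higher. Proliferation genes had 9 of 27 higher and 0 lower (9 adjusted over the list alone), with a small median of 0.21 (camera adjusted p = 0.000988, and adjusted p = 0.570 with an estimated correlation), among them Ccne1, 1.86-fold higher. Interferon-stimulated genes had 3 of 19 higher and 0 lower, with 0 adjusted over the list alone (median 0.46, camera adjusted p = 0.0375, and adjusted p = 0.764 with an estimated correlation). This call was lost without EED knockout replicate 1 or 2 or double knockout replicate 1 or 3 (0.118 to 0.182) and with fry (0.268). Its median was 0.30 without EED knockout replicate 2, 0.28 without double knockout replicate 3, 0.75 without EED knockout replicate 3 and 0.94 in the 6 female libraries only.

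Markers of other cell types were also measured in this comparison. Of 18 lymphocyte markers 0 were higher and 1 lower, with 0 adjusted over the list alone (median -1.47, camera adjusted p = 0.0236, and adjusted p = 0.764 with an estimated correlation). Myeloid markers had 0 of 14 higher and 2 lower, with 1 lower adjusted over the list alone (median -0.68, camera adjusted p = 0.0236, and adjusted p = 0.764 with an estimated correlation). Both calls were lost without EED knockout replicate 1 (0.425 and 0.147, medians -0.38 and -0.36), without double knockout replicate 3 (0.130 and 0.124) and with fry (0.327 and 0.231). The myeloid median was -1.04 in the 6 female libraries only. Of 14 mesenchyme markers 0 changed (median -0.34, range -0.61 to -0.09 with 1 library left out, camera adjusted p = 0.184). The list was called lower without EED knockout replicate 3 (0.0424) and in the 6 female libraries only (median -0.77, 0.0161). The other lists were not called, with camera adjusted p from 0.0704 to 0.876: HOX clusters (7 of 30 higher, 2 lower), PRC2 subunits (1 of 12 higher, 1 lower), stem cell and WNT targets (7 of 22 higher, 4 lower), fetal and regenerative epithelium (4 of 15 higher, 1 lower), tuft cells (0 of 12), MHC class II (1 of 7 lower), immediate early and heat shock genes (1 of 14 higher, 1 lower), mitochondrially encoded transcripts (0 of 13) and sex-linked transcripts (0 of 5). Mitochondrially encoded transcripts (median -0.61, camera adjusted p = 0.0704) were called lower with no low-count filter (0.0169), without EED knockout replicate 3 (median -0.94, 0.000917), without double knockout replicate 2 (median -1.15, 0.0105) and in the 6 female libraries only (median -1.44, 3.03e-05). Tuft cell genes were called lower without double knockout replicate 1 (median -0.51 against -0.33, 0.0115) and MHC class II genes without double knockout replicate 2 (median -0.45 against -0.22, 0.0453). The median and the mean differ in sign for HOX clusters (-0.07 and 0.55), whose test direction followed the mean, and for intestinal regional transcription factors (-0.04 and 0.17), whose test followed the median.

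Without EED knockout replicate 2 the count of changed genes fell to 1984, 1033 higher and 951 lower. Camera with its preset correlation called 10 of 25 lists here and 5 to 12 lists in the 9 other ways of splitting these 6 libraries into 3 and 3. Its list calls therefore do not by themselves set this split apart. The other splits called 0 genes. Each of them mixes libraries of the 2 groups, so it keeps part of the real difference and adds the rest to the spread. They therefore do not show what would be called without a difference.

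**Figure D2:**
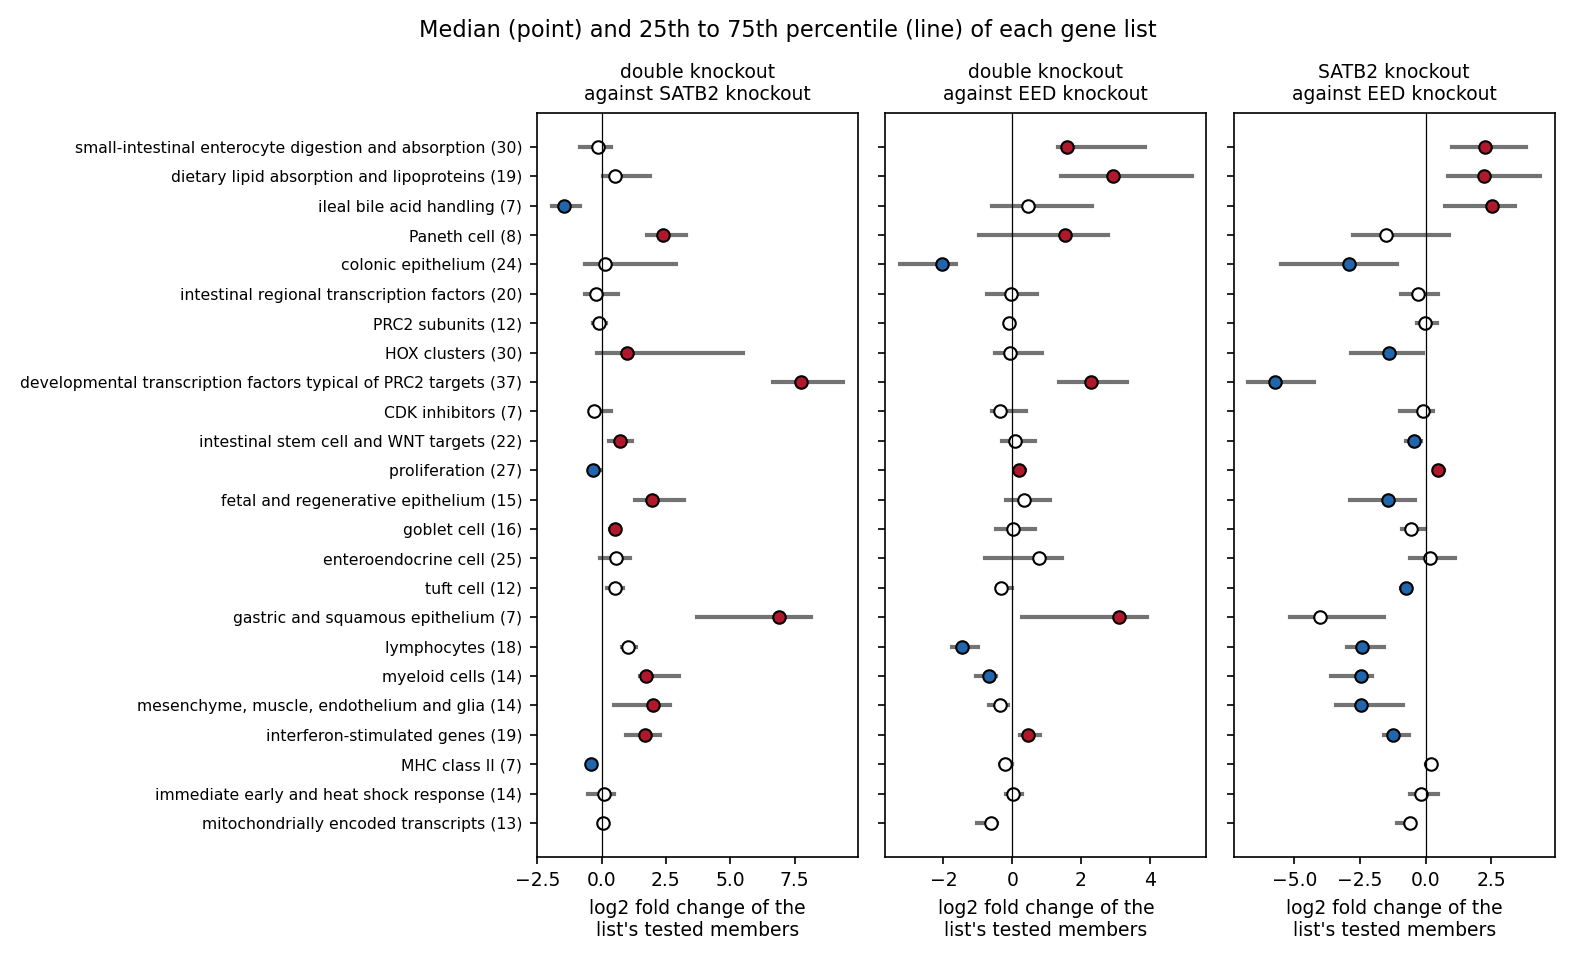
Median (points) and 25th to 75th percentile (lines) of the fitted log2 fold changes of each list's tested members (number in brackets) in the 3 comparisons. The list of sex-linked transcripts is not drawn. Filled points are lists called by camera with the preset correlation, red for higher and blue for lower in the group named first. Open points were not called. The small-intestinal enterocyte list has medians of -0.14, 1.59 and 2.27 and the colonic epithelium list 0.13, -2.06 and -2.91 from the left to the right panel.

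The SATB2 knockout against the EED knockout sets the single knockouts side by side. Of 30 small-intestinal enterocyte genes 24 were higher in the SATB2 knockout, and of 24 colonic epithelium genes 16 were lower (list adjusted p = 0.337 for both with an estimated correlation). Sis (chromosome 3, 72888557 to 72967863), the brush-border sucrase-isomaltase, stood at 3782 ± 1147 against 14.2 ± 2.88 CPM, a 265-fold difference. Fabp6 (chromosome 11, 43596049 to 43601540) stood at 1938 ± 266 against 24.1 ± 8.14 CPM, and Sult1a1, a sulfotransferase of the colonic list, at 0.713 ± 0.833 against 150 ± 48.2 CPM. In all, 4715 of 15924 tested genes changed, 1947 higher and 2768 lower in the SATB2 knockout, of which 501 higher and 1928 lower genes differed at least 2-fold.

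The small-intestinal enterocyte list had 24 of 30 members higher and 0 lower (24 adjusted over the list alone), with a median of 2.27 (camera adjusted p = 4.40e-14, and adjusted p = 0.337 with an estimated correlation). Rbp2 was 44.5-fold, Slc13a1 16.7-fold and Ace2 12.2-fold higher. In dietary lipid absorption 14 of 19 were higher and 2 lower (15 and 2 adjusted over the list alone; median 2.24, camera adjusted p = 2.59e-07, and adjusted p = 0.337 with an estimated correlation), with Apob 7.65-fold higher and Pck1 5.44-fold lower. Ileal bile acid handling had 6 of 7 higher and 0 lower (6 adjusted over the list alone; median 2.55, camera adjusted p = 0.000350, and adjusted p = 0.337 with an estimated correlation), with Fabp6 80.6-fold and Slc10a2 5.84-fold higher. Colonic epithelium genes had 0 of 24 higher and 16 lower (20 adjusted over the list alone), with a median of -2.91 (camera adjusted p = 4.15e-09, and adjusted p = 0.337 with an estimated correlation). Sult1a1 was 191-fold, Nxpe2 62.5-fold and Aqp4 10.7-fold lower. Without SATB2 knockout replicate 1 or 2, the log2 fold change was -10.16 or -6.77 for Sult1a1 (-7.57 with both) and -7.11 or -5.36 for Nxpe2 (-5.97 with both). The largest rises under the naming rule also included Spink12 (at least 181-fold), Cfhr2 (631-fold), Oas1f (count ratio 152, exact 95% interval 41.5 to 1259) and the anion exchanger gene Slc26a6 (122-fold). The log2 fold change of Spink12, 10.77, was 10.09 without SATB2 knockout replicate 2, that of Cfhr2, 9.30, was 9.95 without EED knockout replicate 3, and that of Oas1f, 6.98, was 9.85 without EED knockout replicate 1. By fitted log2 fold change, which for a group at 0 counts lies beyond the bound given here, the largest falls under the naming rule were those of the scaffold gene Mpdz (at least 173-fold), Klk1b22 (at least 78.1-fold), Six3 (at least 74.0-fold), Gbp2b and Mptx1. Mptx1, a pentraxin of the gut epithelium, stood at 0.108 ± 0.0218 against 57.7 ± 49.2 CPM. The calls of Gbp2b and Mptx1 (adjusted p = 0.0198 and 0.00918) were lost without SATB2 knockout replicate 1 (0.141 and 0.0874) or 2 (0.105 and 0.0620). The log2 fold change of Gbp2b, -10.19, was -9.35 without EED knockout replicate 1, and that of Mptx1 was -8.07 without EED knockout replicate 2. With limma voom Gbp2b, Mptx1 and Six3 lost their calls (adjusted p of 0.379, 0.243 and 0.0611).

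Developmental transcription factors typical of PRC2 targets had 1 of 37 higher and 26 lower in the SATB2 knockout (1 and 31 adjusted over the list alone), with a median of -5.72, or -3.02 with the 24 members that had no reads in 1 group at their bound (camera adjusted p = 3.14e-09, and adjusted p = 0.347 with an estimated correlation). The higher member was Tbx3, at 155 ± 15.7 against 42.8 ± 14.1 CPM. Members without reads in the SATB2 knockout could differ only by being lower there. HOX clusters had 0 of 30 higher and 16 lower (1 and 16 adjusted over the list alone; median -1.37, camera adjusted p = 0.000350, and adjusted p = 0.337 with an estimated correlation), with Hoxa7 4.60-fold and Hoxa13 5.77-fold lower. Cdkn2a had 24.1 ± 6.64 CPM in the EED knockout, 451 times the SATB2 knockout by counts (exact 95% interval 125 to 3731). Its log2 fold change of -8.66 was -11.78 without SATB2 knockout replicate 1 and -7.86 without replicate 2. Among the 12 PRC2 subunits and partners 5 were higher and 3 lower (camera adjusted p = 0.566), with Epop 6.32-fold lower and Suz12 1.67-fold higher. Proliferation genes had 19 of 27 higher and 0 lower (22 adjusted over the list alone; median 0.49, camera adjusted p = 4.15e-09, and adjusted p = 0.337 with an estimated correlation), Top2a by 1.78-fold. Fetal and regenerative epithelium had 2 of 15 higher and 9 lower (2 and 11 adjusted over the list alone; median -1.43, camera adjusted p = 0.00118, and adjusted p = 0.347 with an estimated correlation), with Anxa1 6.28-fold and Clu 7.10-fold lower (Clu log2 fold change -2.83, or -3.48 without SATB2 knockout replicate 1). Stem cell and WNT targets had 0 of 22 higher and 10 lower (1 and 11 adjusted over the list alone; median -0.44, camera adjusted p = 0.00465, and adjusted p = 0.347 with an estimated correlation). Interferon-stimulated genes had 0 of 19 higher and 11 lower (1 and 14 adjusted over the list alone; median -1.24, camera adjusted p = 0.00352, and adjusted p = 0.582 with an estimated correlation), with Isg15 4.06-fold lower.

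Among markers of other cell types, mesenchyme markers had 0 of 14 higher and 9 lower (9 adjusted over the list alone; median -2.47, camera adjusted p = 0.000350, and adjusted p = 0.347 with an estimated correlation), with a median of -1.63 with no low-count filter and Col3a1 at 1.61 ± 0.352 against 14.0 ± 3.50 CPM. Myeloid markers had 0 of 14 higher and 10 lower (12 adjusted over the list alone; median -2.47, camera adjusted p = 0.000126, and adjusted p = 0.424 with an estimated correlation). Lymphocyte markers had 0 of 18 higher and 6 lower (8 adjusted over the list alone; median -2.42, camera adjusted p = 0.0125, and adjusted p = 0.693 with an estimated correlation), a call lost without EED knockout replicate 1 (0.0969, median -1.58), without SATB2 knockout replicate 2 (0.0555) and with fry (0.159). Tuft cell genes had 0 of 12 higher and 2 lower (median -0.74, camera adjusted p = 0.0125, and adjusted p = 0.582 with an estimated correlation). Paneth cell genes were mixed, with 2 of 8 tested members (of 17 on the list) higher and 3 lower (camera adjusted p = 0.673). Lyz1 was 12.4-fold higher and the colipase gene Clps 9.39-fold lower. Not called either were goblet cell (3 of 16 higher, 7 lower), enteroendocrine cell (6 of 25 higher, 6 lower), gastric and squamous epithelium (0 of 7 higher, 3 lower), intestinal regional transcription factors (7 of 20 higher, 7 lower), CDK inhibitors (1 of 7 higher, 2 lower), MHC class II (0 of 7), immediate early and heat shock genes (4 of 14 higher, 3 lower), mitochondrially encoded transcripts (0 of 13) and sex-linked transcripts (0 of 5), with camera adjusted p from 0.0921 to 0.933. Mitochondrially encoded transcripts (median -0.58, camera adjusted p = 0.252) were called lower without EED knockout replicate 3 (median -0.90, 0.0114) and in the 6 female libraries only (median -0.90, 0.00438). With fry the lists of CDK inhibitors (0.00102), goblet cells (0.0343) and gastric epithelium (0.0183) were called lower, the last also without EED knockout replicate 2 (median -4.62 against -4.03, 0.0347). For immediate early and heat shock genes the median (-0.17) and the mean (0.08) differ in sign. For PRC2 subunits the median (-0.03) and mean (-0.08) were negative while camera's direction was positive.

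Without SATB2 knockout replicate 1 the count of changed genes fell to 2288 (868 higher and 1420 lower), and without replicate 2 it was 1695 higher and 1617 lower, 51.2% higher against 41.3% with all libraries. Upper-quartile scaling gave 1448 higher and 3035 lower (32.3% higher), and without EED knockout replicate 2 there were 1264 higher and 2193 lower.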

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

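The settings for sex and for the authors' symbols were chosen only after the result was seen. No gene called both in the reported fit and under another setting changed sign. A log2 fold threshold of 1 (glmTreat) left 701, 481 and 1035 genes in the double against the SATB2 knockout, the double against the EED knockout and the SATB2 against the EED knockout. Leaving out 1 library gave 1210 to 3642, 1984 to 3287 and 2288 to 4839 genes. Where this left 1 SATB2 knockout library, it is assumed to vary like the other groups. A lower count there mixes the loss of replication with any trait of the library left out. The other settings stayed within 1.5 times of the reported counts: 6 female libraries only gave 2951, 2800 and 4535, sex as a covariate 2686, 3182 and 3967, the DESeq2 test 4188, 3828 and 5144, limma voom 3417, 3515 and 4199, and counting only symbols that the authors normalized gave 3634, 3428 and 4601. Correlations of deviations between groups were -0.139 to 0.19 for libraries of the same replicate number and -0.203 to 0.268 for others. These few values, which depend on each other, showed no pairing by number but cannot exclude it. The replicate block gave 3187, 3244 and 4272. With the block, lists called in addition were small-intestinal enterocytes (0.0483, lower) and lymphocytes (0.0130, higher) in the double against the SATB2 knockout and mitochondrially encoded transcripts (lower) in the double (0.0210) and the SATB2 (0.0123) against the EED knockout. Not called with it were MHC class II (0.0715) in the double against the SATB2 knockout, and, of the genes in the report, Hsd3b3 (0.0727), St6galnac1 (0.0557), Car1 (0.0571) and, in the last comparison, Six3 (0.0510).

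With the estimated inter-gene correlation camera called 0, 0 and 0 of 25 lists, against 13, 10 and 14. The medians are computed without that setting, so they are the same by construction and do not show that the list calls hold. In the double against the SATB2 knockout they were -1.470 (bile acid), 2.383 (Paneth) and 7.765 (developmental transcription factors). In the double against the EED knockout they were 1.593 (small-intestinal enterocyte), 1.523 (Paneth), -2.056 (colonic) and 2.303 (developmental transcription factors). In the SATB2 against the EED knockout they were 2.266 (small-intestinal enterocyte) and -2.905 (colonic). Leaving out 1 library gave 12 to 14, 6 to 13 and 13 to 15 lists. Fry ended the calls of myeloid cells (0.0708) and MHC class II (0.203) in the first comparison, of lymphocytes (0.327), myeloid cells (0.231) and interferon-stimulated genes (0.268) in the second and of lymphocytes (0.159) in the last. It added the CDK inhibitors in all 3, enteroendocrine cells in the second and goblet cells and gastric epithelium in the last. The Paneth list in the double against the EED knockout was not called with the replicate block (1.485, adjusted p = 0.0648), and ranged from 1.255 to 1.898 with 1 library left out.

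With 1 library left out, Satb2 ranged from -1.469 to -1.006 in the double against the SATB2 knockout. In the SATB2 against the EED knockout it ranged from -0.531 to -0.354 (-0.447 with only the 2 groups compared, edgeR adjusted p = 0.0225). Eed, not called in the double against the EED knockout, was 0.030 with 6 female libraries only and ranged from -0.101 to 0.032 with 1 library left out.

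Camera had not called the following lists, whose test direction changed while some medians kept their sign. In the double against the SATB2 knockout these were, with fry, CDK inhibitors (-0.277, called higher, adjusted p = 0.00502), immediate early (0.101) and mitochondrially encoded transcripts (0.038), with the replicate block mitochondrially encoded transcripts (0.362), and with sex as a covariate sex-linked transcripts (-0.077). With 1 library left out they were colonic epithelium (0.027 to 0.492), CDK inhibitors (-0.284 to -0.064), immediate early (-0.022 to 0.146), mitochondrially encoded (-0.257 to 0.299) and sex-linked transcripts (-0.295 to 11.235). In the double against the EED knockout they were, with 6 female libraries only, intestinal regional transcription factors (0.053) and sex-linked transcripts (0.292), and with 1 library left out goblet cell (-0.179 to 0.148), immediate early (-0.104 to 0.066) and sex-linked transcripts (-0.780 to 0.871). In the SATB2 against the EED knockout they were immediate early with no low-count filter (-0.127), the replicate block (-0.199), 6 female libraries only (-0.236), sex as a covariate (-0.170) and 1 library left out (-0.234 to -0.078), and sex-linked transcripts with 6 female libraries only (-0.001) and 1 library left out (-11.827 to 0.580). Medians of other lists that were not called also moved by over 1.5 times with 1 library left out: in the double against the SATB2 knockout PRC2 subunits (-0.171 to -0.087), in the double against the EED knockout bile acid (0.195 to 0.704), PRC2 subunits (-0.104 to -0.023), HOX clusters (-0.301 to 0.213), stem cell (-0.018 to 0.158) fetal epithelium (0.020 to 0.814), regional transcription factors (-0.100 to 0.037), tuft cell (-0.513 to -0.146), MHC class II (-0.454 to -0.053) and mitochondrially encoded transcripts (-1.150 to -0.187), and in the SATB2 against the EED knockout Paneth (-1.675 to -0.508), goblet (-0.679 to -0.320), enteroendocrine (0.031 to 0.243), gastric (-4.625 to -2.393), MHC class II (0.106 to 0.337), CDK inhibitors (-0.137 to -0.004), PRC2 subunits (-0.030 to 0.053) and mitochondrially encoded transcripts (-0.913 to -0.226). The cause of these changes was not tested.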

Other observations

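The tests on the developmental transcription factors and the bile acid genes were chosen only after the result was seen, and the genes of the next paragraph and the 5 genes of the last one were chosen after their values were seen.

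The gasdermin C genes, which encode pore-forming proteins of the gut epithelium, were lower in the groups with Satb2 targeted. Gsdmc2 stood at 361 ± 71.4 CPM in the EED knockout, 46.3 ± 39.8 CPM in the double knockout and 7.09 ± 3.12 CPM in the SATB2 knockout (edgeR adjusted p = 0.0250 for the double and 0.00668 for the SATB2 against the EED knockout). Gsdmc4 stood at 469 ± 69.6, 65.3 ± 53.5 and 6.86 ± 4.10 CPM (adjusted p = 0.0319 and 0.00640). Genes of the imprinted Dlk1 to Meg3 region were near 0 in the SATB2 knockout, where the mesenchyme list was also lower (median -2.47 against the EED knockout). Meg3 stood at 27.1 ± 10.9 CPM in the EED knockout, 52.8 ± 28.1 CPM in the double knockout and 0.588 ± 0.0431 CPM in the SATB2 knockout (adjusted p = 0.00454 for the double against the SATB2 knockout and 0.00547 for the SATB2 against the EED knockout). The protein-coding Dlk1 stood at 20.4 ± 8.58, 14.9 ± 13.4 and 0.426 ± 0.0104 CPM (adjusted p = 0.0274 and 0.0169). Of the disaccharidase genes, Sis was lower in the double than in the SATB2 knockout (log2 fold change -1.93, edgeR adjusted p = 0.0217), as was Treh above. Only the lactase gene Lct was higher among those named, at 9.15 ± 8.32 against 0.108 ± 0.0218 CPM (edgeR adjusted p = 0.00931). Unlike the genes named by the rule, Gsdmc2, Gsdmc4, Meg3, Dlk1 and Lct were not followed under other settings or with 1 library left out. Nor was Sis in the double against the SATB2 knockout.

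Of the 10 splits of the 6 EED and double knockout libraries, 1 (the real one) called as many as 3509 genes. The highest other split called 0 with edgeR, with 138 to 1185 genes at an unadjusted p under 0.05 against 5561. For the medians, 1 split was as far from 0 as the small-intestinal enterocyte list (1.593, highest other 0.878), 1 as the colonic epithelium list (-2.056, highest other 0.8185) and 1 as the developmental transcription factor list (2.303, highest other 0.9717). For the number of lists called, 4 splits had as many as the real 10, the highest other having 12. The splits are too few for a share under 0.05. Each other split mixes libraries of the 2 groups, so it keeps part of the real difference and adds the rest to the spread. The other splits therefore do not show what would be called, or how large a median would be, without a difference.

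Developmental transcription factors had 23 of 37 members higher in the double than in the EED knockout (adjusted p = 0.488 with an estimated correlation). Some members, such as Zic2, passed the filter only through the double knockout, which favoured a rise. Cells of the lamina propria or muscle could carry such transcripts, but the 75th percentile of the mesenchyme list was -0.1122, below the median of 2.303, which argues against them. A larger share of cells with intact Eed in the EED knockout libraries stays open. If intact cells held Eed at the SATB2 knockout level it would have needed 79.7% intact cells and an Eed log2 fold change of -1.44, and the lower 95% limit was -0.303, but no group with both genes intact was measured to give that level. The loss of SATB2 stays open as a biological explanation and was not tested.

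Bile acid handling had 5 of 7 genes lower in the double than in the SATB2 knockout (median -1.47, adjusted p = 0.212 with an estimated correlation), of which Fabp6 and Slc10a2 lost their calls without SATB2 knockout replicate 1. Fewer mature enterocytes might lower them, but the 25th percentile of the lipid absorption list was 0.03688, which argues against a loss of enterocytes in general as the whole cause. The enterocyte list had 8 of 30 genes lower and 4 higher (median -0.14, 25th percentile -0.82) and was called lower in some settings, such as without double knockout replicate 3 (-0.221, adjusted p = 0.0267), so a partial share of this explanation, or a loss of one kind of enterocyte, stays open. Less complete Satb2 deletion in the double knockout libraries stays open: Satb2 was lower there (-1.172), but the SATB2 knockout held 72.6% of the EED knockout level, which incomplete deletion and reads from exons outside the deleted part would both give. The loss of EED stays open as a biological explanation and was not tested.

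Gbp2b, Hmga1b, Gm6969, BC049987 and St6galnac1 were expressed in at least 1 group and near 0 in another. St6galnac1 also differed within the EED knockout, at 0.128 CPM in replicate 1 and 35.2 and 38.9 CPM in replicates 2 and 3. Sequence of another strain carried with the targeted Satb2 or Eed locus could give such differences. However, 0 of the 5 lie within 10 Mb of either locus, which leaves unlinked strain variants open. Other genes with such a pattern, such as Mpdz and Klk1b22, were not checked for this. Within 10 Mb of Satb2, 26 of 102 genes were called in the double against the EED knockout, against 3475 of 15735 elsewhere (odds ratio 1.21, 95% interval 0.741 to 1.91, Fisher's exact p = 0.403). Within 10 Mb of Eed, 33 of 128 genes were called in the double against the SATB2 knockout, against 3661 of 15709 elsewhere (odds ratio 1.14, interval 0.744 to 1.72, Fisher's exact p = 0.529). These intervals leave an effect of linked sequence undecided.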
